A study of Rattus norvegicus with 17 samples.

How the data were processed

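Liver RNA from 17 male rats was measured with 1 rat genome array per animal: 5 rats given corn oil and 3 rats at each of 4 daily amounts of isopropylated phenol phosphate, with pieces of the left lobe taken on the day after the last of 4 daily doses. Groups and amounts were taken from the sample labels, and replicate numbers name rats within a group and were not used as pairs in the main fit. The deposited values are log2 values that the authors made with RMA (background correction, quantile normalization and summary per probe set; software and version are not given in the sources used here). They ran from 2.61 to 15.4 with array medians of 6.29 to 6.40. No array was left out of the main fit, and all 17 columns matched a label. The signal files behind these values were not analysed here.

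The file held 31099 probe sets, of which 57 were control probe sets, 20826 carried 1 gene symbol, 436 several and 9780 none in the platform table, whose annotation is from 2016. Of those with 1 symbol, 20758 matched the gene reference by gene ID and 0 symbols changed. Each of 14217 genes was represented by its probe set with the highest mean over all arrays, which was a choice between probe sets for 4525 genes. No filter on signal was used.

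Differences were tested with limma 3.58.1 in R 4.3.3 by 1 linear model over all arrays with the 5 groups as a factor and moderated variances that follow the mean signal (eBayes with trend). Each dose was set against vehicle, each dose against the one beneath it, and the rank of the group (0 to 4) was fitted as a slope. P-values were adjusted by Benjamini-Hochberg within each comparison, and an adjusted p under 0.05 counted as a call. All doses shared the 5 vehicle rats, so errors of their differences are correlated. The correlation to expect from that alone was simulated with 100 sets of unchanged groups and compared with differences computed from separate vehicle rats over 10 splits.

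Gene lists were tested with limma's camera, with a preset correlation of 0.01 between members, over 34 lists with at least 4 measured members, adjusted by Benjamini-Hochberg within each comparison. The lists, fixed before the data were examined, covered CAR and PXR, AhR, NRF2, PPARA, growth hormone and STAT5, ATF4, p53 and thyroid hormone targets, cholesterol, fatty acid and bile acid genes, serine esterases, male- and female-predominant genes, the unfolded protein response, cell cycle, acute phase, gluconeogenesis, amino acid catabolism, heme, complement, the circadian clock, 2 liver zones and 10 groups of cell type markers. Hepatocyte, macrophage, stellate cell, endothelial, cholangiocyte, lymphocyte, neutrophil, red cell, pancreas and adipocyte markers made up the latter. List members without a probe set of their own symbol, such as Cyp2b1, were not analysed here. The mean over members minus the vehicle mean gave each rat a list score.

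Genes named in the text followed a rule fixed before the data were examined. Among called genes whose treated rats all lay outside the vehicle range, the 10 largest rises and 10 largest falls were named at 611 mg/kg and 5 of each at the other doses. Between neighbouring doses 3 of each were named, and for the slope 5 of each by smallest p. From each list up to 4 members with the smallest p could be named, or all that passed where 5 or fewer did. Genes named outside this rule are given as named after their values were seen.

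The test, the samples, the lists and most alternatives were fixed before the data were examined. Alternatives were the mean over probe sets, all probe sets, omission of the dimmest 40% of genes, median centring, a repeated quantile normalization, array weights, eBayes without trend or robust, a replicate block, each pair of groups alone, leaving out each rat, stricter thresholds, Welch's test, the dose in mg/kg, the slope without the 611 mg/kg group, camera with an estimated correlation and fry. A fit without 3 arrays that stood apart, the 3' minus 5' GAPDH control difference as a covariate, and the slope over the treated rats alone were chosen after the data were seen. RNA quality was compared by exact permutation of group labels.

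The precision was tested on simulated data for the 611 mg/kg comparison over 14217 genes, in 20 sets with 200 changed genes each. Changes of 0.5, 1 and 2 on the log2 scale were recovered in 64.8%, 97.4% and 99.8% of cases, and 5.05% of calls were false. The real arrays were unequal, with array weights of 5.04 for 76.5 mg/kg rat 1 and 0.267 for 76.5 mg/kg rat 3. Whether the simulated rates hold for such arrays was not tested. Simulated lists of 15 genes shifted by 0.5 had an unadjusted camera p under 0.05 in 100% of cases and unshifted lists in 5%. These rates describe the simulated lists only. Regrouped real rats, described in the closing part, gave as many called lists as the real groups in 37 of the 56 splits at 76.5 mg/kg. At 153 mg/kg they did so in 29 of the 56 splits. The 5% is therefore not a rate of false calls for the real lists.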

Results

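Liver RNA was measured on 1 oligonucleotide array per animal in 17 male Sprague Dawley rats given isopropylated phenol phosphate (IPP), an aryl phosphate flame retardant and plasticizer, or its corn oil vehicle by gavage. Vehicle was given to 5 rats and each of 4 daily amounts, 76.5, 153, 305.5 and 611 mg/kg body weight, to 3 rats. The treatment protocol rounds 76.5 and 305.5 to 77 and 306 mg/kg. In moles the smallest amount was 0.169 and the largest 1.35 mmol/kg. Values were deposited on a log2 scale and ran from 2.61 to 15.4, with array medians between 6.29 and 6.40 and correlations between pairs of arrays from 0.975 to 0.996. The number of arrays limits the precision of every difference below. Differences are given as log2 dose minus vehicle ± SE from 1 limma fit over all 17 arrays, with n = 3 per dose and n = 5 for vehicle, over 14217 genes. Where the lower group mean of a difference lay under log2 6, near background, the size is read as a lower bound. This holds for the rises of Nr1d1, Dbp, Nfe2, Mki67, Ccna2, Bub1 and Ect2 and the falls of Spin2b, Lox, Socs2 and Abcg8. Every gene named as a largest rise or fall against vehicle had all 3 treated rats outside the range of the 5 vehicle rats.

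Arrays from 3 rats stood apart from the rest. The array of 611 mg/kg rat 2 had the largest 3' minus 5' signal difference of the GAPDH control probe sets, 2.89 against 0.93 to 1.56 on the other 16 arrays, and of the actin control probe sets, 3.83 against 1.93 to 3.06. Its median correlation with the other arrays was 0.985, and those of 76.5 mg/kg rats 2 and 3 were 0.988 and 0.986. The GAPDH difference averaged 1.37 ± 0.18 (SD, n = 5) in vehicle and 1.70 ± 1.03 (SD, n = 3) at 611 mg/kg. No dose group was called apart from vehicle in either control difference (two-sided exact permutation p from 0.232 to 0.893 over 56 splits each, 8 comparisons, Benjamini-Hochberg adjusted p from 0.738 to 0.893). With 56 splits a lone difference could not have passed after adjustment over 8 comparisons, so a difference in a single group was not excluded.

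The first question of the design was which liver genes differed from vehicle at the smallest amount. For the clock genes a different clock phase at necropsy stays open at every dose, as set out in the closing part. Any other gene or list that varies over the day shares this limit, and which of those below do so was not tested. At 76.5 mg/kg the genes with the largest rise were clock genes and a drug exporter. Nr1d1 and Nr1d2, which encode the REV-ERB repressors of the circadian clock, rose by 2.87 ± 0.22 (limma, Benjamini-Hochberg adjusted p = 3.17e-06), and by 1.35 ± 0.12 (adjusted p = 2.49e-05). Dbp, a transcription factor driven by the clock, rose by 2.34 ± 0.38 (adjusted p = 0.0145). Cry1, a clock repressor, fell by 0.93 ± 0.16 (adjusted p = 0.0204). Abcc3, an organic anion exporter, rose by 2.29 ± 0.36 (adjusted p = 0.0140), and Nceh1, a hydrolase of neutral cholesterol esters, by 1.58 ± 0.27 (adjusted p = 0.0193). The largest falls were those of the taurine transporter gene Slc6a6 (fell by 1.59 ± 0.29, adjusted p = 0.0232) and of Spin2b (fell by 1.17 ± 0.21, adjusted p = 0.0207). Next came the N-acetyltransferase gene Nat8 (fell by 1.15 ± 0.19, adjusted p = 0.0145), Sez6 (fell by 1.07 ± 0.13, adjusted p = 0.000656) and the glucocorticoid-induced gene Tsc22d3 (fell by 0.98 ± 0.17, adjusted p = 0.0188).

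Among the fixed gene lists, targets of the xenobiotic receptors CAR and PXR rose at 76.5 mg/kg as a group. Of 15 measured members 3 passed the test, Ces2c (1.30 ± 0.16, adjusted p = 0.000656), Abcc3 and Ugt2b1 (0.89 ± 0.17, adjusted p = 0.0325), and 5 when adjusted over the list alone. The list mean lay above every vehicle rat in 3 of 3 rats (median log2 difference 0.22, camera adjusted p = 0.000553). With an estimated correlation between members the call was lost (adjusted p = 0.583). The NRF2 and glutathione list (median 0.19, camera adjusted p = 0.0163) and the ATF4 and amino acid response list (median 0.39, camera adjusted p = 0.0228) were also called higher, with 0 of 25 and 0 of 17 members past the test. Lists of male-predominant liver genes (median -0.12, camera adjusted p = 0.0349) and periportal hepatocyte genes (median -0.09, camera adjusted p = 0.0228) were called lower with 0 of 9 and 0 of 11 members past it. The male-predominant and periportal calls were lost in 11 and 7 of 30 alternatives, among them without the 3 arrays that stood apart (adjusted p = 0.545 and adjusted p = 0.287). The ATF4 call was lost in 8 of 30, among them without vehicle rat 1, 3 or 5, without treated rat 1 and with the GAPDH covariate, and the NRF2 call in 3 of 30, among them without treated rat 1. With an estimated correlation these 4 lists gave adjusted p = 0.595, 0.595, 0.595 and 0.583. In the clock list 3 members rose, 1 fell and 12 did not pass, and the list was not called (camera adjusted p = 0.453), although its mean lay above every vehicle rat in 3 of 3 rats. The clock list score averaged 0.27, and the rises of Nr1d1, Nr1d2 and Dbp together exceeded the summed change over all its members. In the esterase list Ces2c and Nceh1 rose while 12 members did not pass (camera adjusted p = 0.662, 3 of 3 rats above vehicle). The esterase score averaged 0.12. The rises of Ces2c and Nceh1 together exceeded the summed change over all 14 members, so the other 12 were lower on average.

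In all, 20 genes were higher and 18 lower at 76.5 mg/kg than in vehicle, 12 of the 38 by at least 1 on the log2 scale, and 1527 had an unadjusted p under 0.05. All 3 treated rats lay outside the vehicle range for 20 and 17 of these genes, and for 6.30% of all genes, where chance gives 3.57%. A fit without the 3 arrays that stood apart left 1 rat at this dose, whose spread was taken from the other groups, and called 9 genes higher and 2 lower. Of the 10 genes named above as largest rises or falls it called Nr1d1 and Nr1d2. Slc6a6 lost its call in 9 of 29 alternatives, among them without vehicle rat 1, 4 or 5 or treated rat 2 or 3. Spin2b lost its call in 7 of 28, among them without vehicle rat 2 or 4 or treated rat 2 or 3. Dbp, Abcc3, Nceh1, Nat8 and Tsc22d3 lost theirs without treated rat 2. Leaving out single rats gave, as higher and lower genes, 12 and 5 without vehicle rat 1, 11 and 7 without vehicle rat 2 and 47 and 46 without treated rat 1. They were 8 and 3 without treated rat 2 and 49 and 34 without treated rat 3, and lower genes numbered 10 and 11 without vehicle rats 3 and 4.

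At 153 mg/kg clock genes lay on both sides of vehicle, and a chemokine and a desaturase gene were lower. Dbp rose by 3.50 ± 0.38 (limma, Benjamini-Hochberg adjusted p = 0.000226), and Nr1d1 by 3.32 ± 0.22 (adjusted p = 3.00e-07). Tef, another output factor gene of the clock, rose by 0.90 ± 0.13 (adjusted p = 0.00200). Of the 16 measured clock genes 5 rose, 4 fell and 7 did not pass. Camera, which sets a list against all other genes, did not call the clock list (adjusted p = 0.137). Fry, which does not, called it higher (adjusted p = 0.00128), with 3 of 3 rats above every vehicle rat. The clock list score averaged 0.45, and the rises of Dbp and Nr1d1 made up most of it. Hsd17b2, an enzyme that inactivates sex steroids, rose by 2.32 ± 0.32 (adjusted p = 0.00177), and Abcc3 by 1.99 ± 0.36 (adjusted p = 0.0147). The chemokine gene Cxcl1 fell by 3.16 ± 0.69 (adjusted p = 0.0420), and the fatty acid desaturase gene Scd by 2.75 ± 0.51 (adjusted p = 0.0161). Cdkn1a, which encodes the cell cycle inhibitor p21, fell by 2.56 ± 0.37 (adjusted p = 0.00213). Slc6a6 fell by 2.01 ± 0.29 (adjusted p = 0.00205) and the tubulin gene Tubb2a fell by 1.66 ± 0.23 (adjusted p = 0.00200).

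The ATF4 and amino acid response list rose at 153 mg/kg, with 3 of 17 members past the test and all 3 rats above every vehicle rat. These were the stress-induced mTOR inhibitor Ddit4 (2.14 ± 0.37, adjusted p = 0.00900), the glutathione-degrading enzyme Chac1 (1.62 ± 0.30, adjusted p = 0.0164) and the pseudokinase Trib3 (1.40 ± 0.28, adjusted p = 0.0264). When adjusted over the list alone 5 were higher and 1 lower. The list's camera adjusted p was 0.00241 and became adjusted p = 0.419 with an estimated correlation. CAR and PXR targets again had 3 of 15 members higher, Ces2c, Ugt2b1 and Abcc3, or 7 higher and 1 lower when adjusted over the list alone. The list mean lay above every vehicle rat in 3 of 3 rats (median 0.23, camera adjusted p = 1.34e-05, adjusted p = 0.312 with an estimated correlation). NRF2 and glutathione genes were called higher with 0 of 25 members past the test, 5 when adjusted over the list alone (camera adjusted p = 0.0114, adjusted p = 0.564 with an estimated correlation). Stellate cell and fibroblast markers were called lower with 0 of 12 members past the test, 3 over the list alone (median -0.18, camera adjusted p = 0.0114, adjusted p = 0.419 with an estimated correlation). PPARA targets were called lower, with 1 member higher and 3 lower over the list alone (camera adjusted p = 0.0428, adjusted p = 0.623 with an estimated correlation). Among them the omega-hydroxylase gene Cyp4a1 fell by 0.72 ± 0.14 (adjusted p = 0.0166), and Fgf21, a fasting hormone, went the other way and rose by 1.71 ± 0.38 (adjusted p = 0.0426).

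At this dose 58 genes were higher and 48 lower than in vehicle, 34 of the 106 by at least 1, and 1688 had an unadjusted p under 0.05. All 58 and 48 had the treated rats outside the vehicle range, as had 12.7% of all genes against 3.57% by chance. With the 3 arrays that stood apart left out 209 genes were higher and 105 lower, and the PPARA list was not called (adjusted p = 0.0652). The PPARA call was lost in 11 of 30 alternatives, 6 of which left out 1 rat, such as vehicle rat 2 or 3 or 153 mg/kg rat 3. The NRF2 call was lost in 5 of 30, among them without 153 mg/kg rat 1, and the stellate cell call in 3 of 30, among them without vehicle rat 3. Leaving out single rats gave 35 and 28 genes without vehicle rat 1, 114 and 73 without 76.5 mg/kg rat 3, 25 and 17 without 153 mg/kg rat 1 and 18 and 11 without 153 mg/kg rat 2. Higher genes numbered 38, 36 and 34 without vehicle rat 2, vehicle rat 4 and 153 mg/kg rat 3. Cxcl1 lost its call in 16 of 29 alternatives, Ddit4 without 153 mg/kg rat 2 or 3, Abcc3 without rat 1 or 2 and Scd without rat 2 of that dose.

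At 305.5 mg/kg the clock genes Dbp and Nr1d1, an exporter and an esterase gene rose, and a chemokine and an immediate early gene fell. Dbp rose by 4.20 ± 0.38 (limma, Benjamini-Hochberg adjusted p = 1.11e-05), beside Nr1d1 (3.32 ± 0.22, adjusted p = 1.51e-07). Abcc3 rose by 2.78 ± 0.36 (adjusted p = 0.000548), Hsd17b2 by 2.58 ± 0.32 (adjusted p = 0.000305) and the carboxylesterase gene Ces2c by 2.31 ± 0.16, or 4.95-fold (adjusted p = 1.51e-07). Cxcl1 fell by 4.13 ± 0.69 (adjusted p = 0.00388), and Egr1, an immediate early transcription factor gene, fell by 2.99 ± 0.52 (adjusted p = 0.00466). Scd fell by 2.75 ± 0.51 (adjusted p = 0.00757), Cdkn1a fell by 2.70 ± 0.37 (adjusted p = 0.000738) and Slc6a6 fell by 2.60 ± 0.29 (adjusted p = 0.000142).

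CAR and PXR targets rose with 7 of 15 members past the test, 9 when adjusted over the list alone, and 3 of 3 rats above every vehicle rat. Besides Ces2c and Abcc3 they included the glucuronosyltransferase gene Ugt2b1 (1.18 ± 0.17, adjusted p = 0.00119) and the retinal dehydrogenase gene Aldh1a1 (0.97 ± 0.16, adjusted p = 0.00347). The list was called with camera's preset correlation (median 0.45, adjusted p = 1.11e-12) and with an estimated one (adjusted p = 0.00972). ATF4 genes rose in the same manner, with Chac1 (2.30 ± 0.30, adjusted p = 0.000557), Trib3 (1.91 ± 0.28, adjusted p = 0.00154), Ddit4 (2.14 ± 0.37, adjusted p = 0.00483) and the mitochondrial folate enzyme Mthfd2 (1.04 ± 0.20, adjusted p = 0.0101) higher and Cth lower among 17 members. Over the list alone 9 were higher and 1 lower, and all 3 rats lay above vehicle (median 0.60, camera adjusted p = 2.88e-08, adjusted p = 0.0492 with an estimated correlation). Growth hormone and STAT5 genes fell as a group, with all 3 rats below every vehicle rat (median -0.30, camera adjusted p = 5.22e-05, adjusted p = 0.00972 with an estimated correlation). Among its 12 members Igfbp3, an IGF-binding protein gene, passed the test (fell by 0.79 ± 0.13, adjusted p = 0.00320), and 5 were lower when adjusted over the list alone. NRF2 and glutathione genes were called higher with 6 of 25 members, 9 over the list alone, among them the epoxide hydrolase gene Ephx1 (0.83 ± 0.17, adjusted p = 0.0168) and the glutathione transferase gene Gsta1 (0.32 ± 0.07, adjusted p = 0.0178). That list's camera adjusted p was 1.88e-07, and adjusted p = 0.0860 with an estimated correlation.

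Lists of endothelial, stellate cell and macrophage markers were called lower at 305.5 mg/kg, with few single members past the test. Of the 9 endothelial markers Pecam1, a cell junction protein gene, fell by 0.37 ± 0.08 (limma, Benjamini-Hochberg adjusted p = 0.0236). Over the list alone 8 were lower (median -0.38, camera adjusted p = 2.75e-07, adjusted p = 0.0703 with an estimated correlation). Of the 12 stellate cell and fibroblast markers the growth factor receptor gene Pdgfrb fell by 0.73 ± 0.15 (adjusted p = 0.0150). Over the list alone 5 were lower (median -0.29, camera adjusted p = 5.48e-06, adjusted p = 0.0860 with an estimated correlation). None of the 10 macrophage markers passed the test over all genes and 4 did over the list alone (median -0.36, camera adjusted p = 9.87e-06, adjusted p = 0.204 with an estimated correlation). The endothelial and stellate means lay below every vehicle rat in 3 of 3 rats each and the macrophage mean in 2 of 3. The list of PPARA targets was called lower (camera adjusted p = 0.00122, adjusted p = 0.473 with an estimated correlation), with 11 of 30 members lower and 3 higher over the list alone. Past the test over all genes were the falls of Angptl4 (fell by 1.89 ± 0.25, adjusted p = 0.000548), Pdk4, Plin2 and Pex11a. Angptl4 inhibits lipoprotein lipase, Pdk4 inhibits pyruvate dehydrogenase and Plin2 coats lipid droplets, so these 3 members are not enzymes of fatty acid oxidation. Cyp4a8, an omega-hydroxylase gene, rose by 1.05 ± 0.20 (adjusted p = 0.00765). Cell cycle genes were called slightly lower with 0 of 25 members past the test (median -0.15, camera adjusted p = 0.0481, adjusted p = 0.751 with an estimated correlation), a call lost in 15 of 30 alternatives. Of the clock genes 6 rose and 4 fell, and the clock list was called higher by fry (adjusted p = 0.00230) and not by camera (adjusted p = 0.288). The clock list score averaged 0.40, and the rises of Dbp and Nr1d1 together exceeded the summed change over all its members.

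In total 107 genes were higher and 209 lower at 305.5 mg/kg, 64 of the 316 by at least 1, and 1920 had an unadjusted p under 0.05. The treated rats lay outside the vehicle range for 105 and 208 of them, and for 13.7% of all genes against 3.57% by chance. Omission of the 3 arrays that stood apart gave 292 higher and 486 lower genes. Leaving out single rats gave 68 and 136 genes without vehicle rat 1, 189 and 336 without 76.5 mg/kg rat 3, and 49 and 95 without 305.5 mg/kg rat 1. They were 56 and 86 without rat 2 and 49 and 102 without rat 3 of that dose, and lower genes numbered 120 without vehicle rat 3. Scd lost its call without 305.5 mg/kg rat 1.

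At 611 mg/kg cell cycle genes and genes of xenobiotic and glutathione enzymes rose, and clock genes were called on both sides of vehicle. Dbp rose by 4.18 ± 0.38 (limma, Benjamini-Hochberg adjusted p = 9.01e-06), Abcc3 by 3.55 ± 0.36 (adjusted p = 4.34e-05), and Nr1d1 by 3.28 ± 0.22 (adjusted p = 1.25e-07). Ces2c rose by 2.80 ± 0.16, or 6.97-fold (adjusted p = 1.99e-08), Hsd17b2 by 2.52 ± 0.32 (adjusted p = 0.000204) and Nr1d2 by 2.03 ± 0.12 (adjusted p = 4.20e-08). Cdkn3, a phosphatase of cyclin-dependent kinases, rose by 2.34 ± 0.39 (adjusted p = 0.00199), and Gsta3, a glutathione transferase gene, by 2.23 ± 0.30 (adjusted p = 0.000408). Nfe2, a transcription factor gene of blood precursors, rose by 2.19 ± 0.57 (adjusted p = 0.0271) and the homeobox gene Meox2 by 1.92 ± 0.43 (adjusted p = 0.0124), and Meox2 lost its call without 611 mg/kg rat 2. Nfe2 lost its call in 8 of 28 alternatives, among them leaving out any 1 of the 3 treated rats or vehicle rat 1, 4 or 5. The largest falls were those of Cxcl1 (fell by 3.60 ± 0.69, adjusted p = 0.00551) and Scd (fell by 3.23 ± 0.51, adjusted p = 0.00129). Next came Slc6a6 (fell by 3.16 ± 0.29, adjusted p = 9.01e-06) and Cdkn1a (fell by 2.52 ± 0.37, adjusted p = 0.000696). Bmal1 (also called Arntl), the activator that Nr1d1 represses, fell by 2.21 ± 0.26 (adjusted p = 0.000131), the clock output repressor gene Nfil3 fell by 1.91 ± 0.27 (adjusted p = 0.000523) and Tubb2a fell by 2.04 ± 0.23 (adjusted p = 0.000129). Lox, a collagen cross-linking enzyme gene, fell by 2.02 ± 0.45 (adjusted p = 0.0122), a call lost without 611 mg/kg rat 3 and with a replicate block. Egr1 fell by 2.35 ± 0.52 (adjusted p = 0.0115) and Socs2, a target of growth hormone signalling, fell by 1.86 ± 0.38 (adjusted p = 0.00741), and both lost their calls without 611 mg/kg rat 2.

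**Figure D1:**
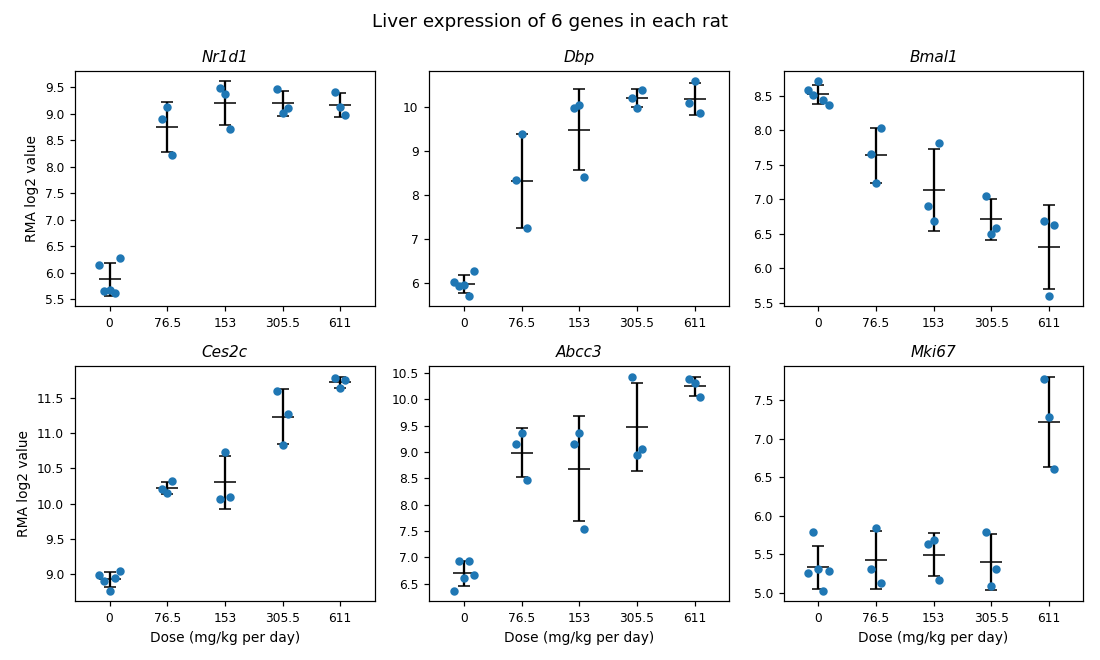
RMA log2 value of 6 genes in each rat (points) against the daily dose in mg/kg body weight, with the mean (wide line) and SD (bars) of each group, n = 5 at dose 0 and n = 3 at each other dose. Nr1d1, Dbp, Ces2c and Abcc3 lay above vehicle in all treated rats and Bmal1 below it. Mki67 reached 5.79 in vehicle and 5.85 at the 3 lower doses, and read 7.78, 7.28 and 6.61 in rats 1, 2 and 3 at 611 mg/kg.

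Of the 25 measured cell cycle genes 12 rose at 611 mg/kg and 13 did not pass, and 18 were higher when adjusted over the list alone. The proliferation marker Mki67 rose by 1.89 ± 0.24 (limma, Benjamini-Hochberg adjusted p = 0.000204), and the S and G2 phase cyclin Ccna2 by 1.83 ± 0.27 (adjusted p = 0.000836). The spindle checkpoint kinase gene Bub1 rose by 1.46 ± 0.19 (adjusted p = 0.000278) and the chromosomal passenger gene Birc5 by 1.04 ± 0.15 (adjusted p = 0.000625). The list mean lay above every vehicle rat in 3 of 3 rats, with 1.12 in rat 1, 0.45 in rat 2 and 0.61 in rat 3 (list median 0.62, camera adjusted p = 2.08e-10). With an estimated correlation the call was lost (adjusted p = 0.151), and without 611 mg/kg rat 2, the array with the largest control differences, 15 members were higher.

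CAR and PXR targets reached 9 of 15 members higher at 611 mg/kg, 12 when adjusted over the list alone, and the list mean lay above every vehicle rat in 3 of 3 rats (median 0.55, camera adjusted p = 8.18e-12, adjusted p = 0.0256 with an estimated correlation). With Ces2c and Abcc3 they included Ugt2b1 (1.44 ± 0.17, limma and Benjamini-Hochberg adjusted p = 0.000131) and Aldh1a1 (1.22 ± 0.16, adjusted p = 0.000322). NRF2 and glutathione genes had 9 of 25 members higher, 10 over the list alone. They were led by Gsta3, Gsta4 (0.84 ± 0.15, adjusted p = 0.00267), Gsta1 (0.38 ± 0.07, adjusted p = 0.00367) and the quinone reductase gene Nqo1 (1.03 ± 0.22, adjusted p = 0.00911). All 3 rats lay above vehicle (camera adjusted p = 3.05e-06, adjusted p = 0.126 with an estimated correlation). Of the 14 measured serine esterases, enzymes that organophosphates can inhibit, Ces2c, Nceh1 (1.21 ± 0.27, adjusted p = 0.0123) and Bche (0.55 ± 0.15, adjusted p = 0.0300) rose. The hepatic lipase gene Lipc fell by 0.30 ± 0.08 (adjusted p = 0.0341), with 4 higher and 1 lower over the list alone. The esterase list was called higher at this dose with a camera adjusted p of 0.00765 and with 3 of 3 rats above vehicle, and its adjusted p was 0.125 with an estimated correlation. The esterase score averaged 0.37, and the rises of Ces2c, Nceh1 and Bche made up most of it. Cholesterol synthesis genes were called higher with Hsd17b7 past the test (0.87 ± 0.23, adjusted p = 0.0298), which was 1 of 20 members, and with 3 of 3 rats above vehicle (median 0.33, camera adjusted p = 0.00693, adjusted p = 0.656 with an estimated correlation), a call lost in 3 of 30 alternatives.

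**Figure D2:**
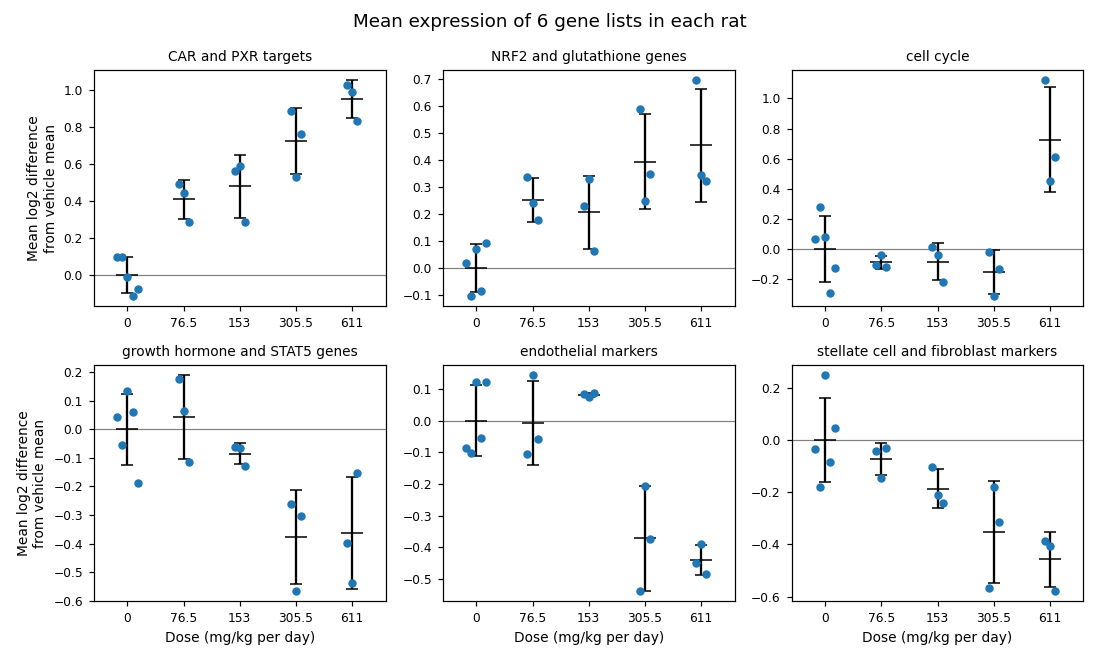
Mean log2 difference from the vehicle mean over the measured members of 6 gene lists in each rat (points) against the daily dose in mg/kg body weight, with the mean (wide line) and SD (bars) of each group, n = 5 at dose 0 and n = 3 at each other dose; the grey line marks 0. CAR and PXR targets averaged 0.41, 0.48, 0.72 and 0.95 from the lowest to the highest dose, and the cell cycle list averaged 0.73 at 611 mg/kg.

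Growth hormone and STAT5 genes were lower at 611 mg/kg as well, with Igfbp3 (fell by 0.76 ± 0.13, limma and Benjamini-Hochberg adjusted p = 0.00211) and Socs2 past the test among 12 members. Over the list alone 4 were lower, and 2 of 3 rats lay below every vehicle rat (median -0.28, camera adjusted p = 0.000902, adjusted p = 0.0334 with an estimated correlation). In the list of PPARA targets, called lower (camera adjusted p = 0.00447, adjusted p = 0.363 with an estimated correlation), Plin2 fell by 0.98 ± 0.14 (adjusted p = 0.000696) and Cyp4a3 and Pdk4 fell, Cyp4a8 rose, and in all 6 members were lower, 1 higher and 23 of 30 not past the test, with 11 lower and 2 higher over the list alone. Plin2 and Pdk4 act on lipid droplets and pyruvate use and are not oxidation enzymes.

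Lists of endothelial, stellate cell, macrophage, lymphocyte and red cell markers were called lower at 611 mg/kg. The scavenger receptor gene Stab2, a marker of sinusoidal endothelium, fell by 0.91 ± 0.13 (limma, Benjamini-Hochberg adjusted p = 0.000703) and Lyve1 fell by 0.71 ± 0.14 (adjusted p = 0.00681). With Pecam1 and Kdr 4 of 9 endothelial markers fell, 7 over the list alone (median -0.39, camera adjusted p = 3.05e-06, adjusted p = 0.115 with an estimated correlation). Pdgfrb fell by 0.80 ± 0.15 (adjusted p = 0.00466). With Tagln and Acta2 3 of 12 stellate cell and fibroblast markers fell, 8 over the list alone (median -0.44, camera adjusted p = 3.05e-06, adjusted p = 0.115 with an estimated correlation). Macrophage markers (median -0.34, camera adjusted p = 0.00447) and lymphocyte markers (median -0.16, camera adjusted p = 0.0341) had 0 of 10 and 0 of 12 members past the test. They gave adjusted p = 0.363 and adjusted p = 0.335 with an estimated correlation. The lymphocyte call was lost in 8 of 29 alternatives, among them leaving out vehicle rat 1, 3 or 4 or 611 mg/kg rat 1 or 3. Of the 4 red cell markers the beta globin gene Hbb fell by 1.63 ± 0.24 (adjusted p = 0.000689) and the erythroid heme enzyme gene Alas2 fell by 1.34 ± 0.23 (adjusted p = 0.00281). All 4 were lower over the list alone (median -0.94, camera adjusted p = 0.000122, adjusted p = 0.122 with an estimated correlation). The endothelial, stellate, lymphocyte and red cell means lay below every vehicle rat in 3 of 3 rats and the macrophage mean in 1 of 3. Hepatocyte markers stayed near vehicle (median -0.03, camera adjusted p = 0.814, 0 of 9 past the test), with albumin (Alb), named after its values were seen, at 15.34 in vehicle and 15.35 at 611 mg/kg, close to the highest value on any array, where a change could not be read.

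Clock genes were called in both directions at 611 mg/kg, 7 higher, 4 lower and 5 not past the test of 16 measured, and camera did not call the clock list (adjusted p = 0.138, adjusted p = 0.334 with an estimated correlation). Fry called it higher (adjusted p = 0.000223), with 3 of 3 rats above every vehicle rat. The clock list score averaged 0.45. The rises of Dbp, Nr1d1 and Nr1d2 together exceeded the summed change over all members, so the other members were lower on average. Beside the rises of Nr1d1, Nr1d2 and Dbp, Npas2, which encodes a stand-in for the Clock protein as partner of Bmal1, fell by 1.56 ± 0.17 (limma, Benjamini-Hochberg adjusted p = 8.40e-05). The AhR list was not called (camera adjusted p = 0.927), although Cyp1a1, its most inducible member, rose by 1.41 ± 0.34 (adjusted p = 0.0194) with Nqo1. Bile acid genes went both ways (camera adjusted p = 0.456). The cholic acid enzyme gene Cyp8b1 rose by 0.82 ± 0.15 (adjusted p = 0.00394) and the nuclear repressor gene Nr0b2 by 1.04 ± 0.27 (adjusted p = 0.0287). The phospholipid exporter gene Abcb4 fell by 0.73 ± 0.13 (adjusted p = 0.00391) and the sterol exporter gene Abcg8 fell by 1.12 ± 0.27 (adjusted p = 0.0201). In fatty acid synthesis Scd fell and Thrsp, a lipogenic gene, rose by 1.08 ± 0.25 (adjusted p = 0.0146), and the list was not called (camera adjusted p = 0.773). Among p53 targets (camera adjusted p = 0.907) Cdkn1a fell, whereas Mdm2 rose by 0.46 ± 0.13 (adjusted p = 0.0368) and Ccng1 by 0.57 ± 0.16 (adjusted p = 0.0422). In the acute phase and inflammation list Cxcl1 was 1 of 21 members past the test (camera adjusted p = 0.790).

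The other lists were not called by camera at 611 mg/kg. Fry called heme enzymes higher (adjusted p = 0.0185) and pancreas (adjusted p = 0.0240) and adipocyte markers (adjusted p = 0.00650) lower, each with 3 of 3 rats outside the vehicle range. Camera's adjusted p was 0.296 for male-predominant and 0.908 for female-predominant liver genes, with 0 members past the test in either. It was 0.907 for the unfolded protein response, where Herpud1 rose by 0.48 ± 0.12 (limma, Benjamini-Hochberg adjusted p = 0.0257). It was 0.0609 for ATF4 genes, where Ddit4 and Trib3 rose by 1.41 ± 0.37 and 1.07 ± 0.28, and 0.927 for gluconeogenesis and glycogen. It was 0.908 for amino acid catabolism, where the transaminase gene Gpt rose by 0.64 ± 0.14 (adjusted p = 0.00987) and Agxt fell by 0.50 ± 0.12 (adjusted p = 0.0196). It was 0.405 for thyroid hormone responsive genes, where Thrsp passed, 0.270 for heme enzymes, where Alas1 rose by 0.94 ± 0.13 (adjusted p = 0.000541), and 0.405 as well for complement and coagulation, where Masp1 fell by 0.52 ± 0.08 (adjusted p = 0.00167) and Serpind1 fell by 0.38 ± 0.11 (adjusted p = 0.0382). Pericentral genes gave 0.456, with Tbx3 and Slc1a2 higher and Gulo lower, and periportal genes 0.907. Cholangiocyte markers gave 0.726, with the adhesion gene Epcam higher by 0.72 ± 0.17 (adjusted p = 0.0167) and Krt7 lower, neutrophil markers 0.296, pancreas markers 0.0592, with the elastase gene Cela1 lower, and adipocyte markers 0.137.

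Counted over all genes, 716 were higher and 344 lower at 611 mg/kg, 118 of the 1060 by at least 1, and 3434 had an unadjusted p under 0.05. The treated rats lay outside the vehicle range for 669 and 328 of them, and for 18.6% of all genes against 3.57% by chance. Omission of the 3 arrays that stood apart gave 569 higher and 310 lower genes, and omission of 611 mg/kg rat 2 alone 257 and 169. Leaving out vehicle rat 5 gave 432 and 229 genes, and 473 and 476 genes were higher without vehicle rat 1 and without 611 mg/kg rat 3.

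**Figure D3:**
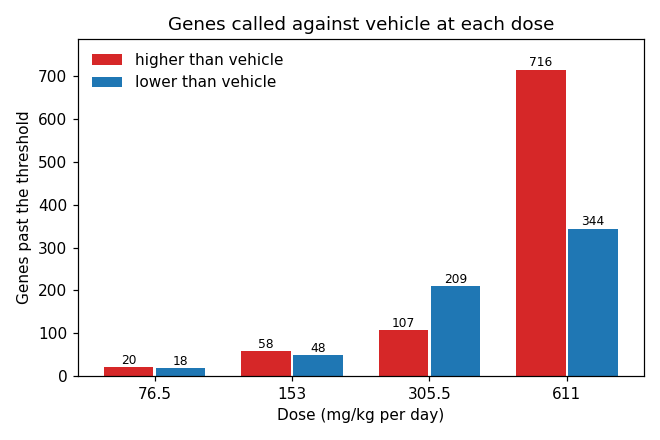
Number of genes with limma adjusted p under 0.05 against vehicle (vertical axis, genes out of 14217 tested) at each daily dose in mg/kg body weight, higher (red bars) and lower (blue bars). The bars read 20 and 18, 58 and 48, 107 and 209, and 716 and 344 genes.

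Neighbouring doses were then set against each other, a comparison that does not use the vehicle arrays for its difference. Between 305.5 and 611 mg/kg cell division genes rose. Cdkn3 rose by 2.41 ± 0.44 (limma, Benjamini-Hochberg adjusted p = 0.0225), Ect2, a regulator of cytokinesis, by 2.31 ± 0.36 (adjusted p = 0.00660) and Ccna2 by 2.22 ± 0.31 (adjusted p = 0.00388). Among the 25 cell cycle genes 8 rose, 20 when adjusted over the list alone, and 24 of 25 had a positive difference (median 0.82, camera adjusted p = 9.26e-19, adjusted p = 0.246 with an estimated correlation). The 3 largest falls were those of Chac1 (fell by 1.66 ± 0.34, adjusted p = 0.0467), Hbb (fell by 1.47 ± 0.26, adjusted p = 0.0203) and Spata2L (fell by 0.59 ± 0.12, adjusted p = 0.0433). ATF4 genes were lower at 611 than at 305.5 mg/kg (median -0.24, camera adjusted p = 0.00286, adjusted p = 0.502 with an estimated correlation), as were red cell markers (camera adjusted p = 0.00175, adjusted p = 0.443 with an estimated correlation). Cholesterol synthesis genes were higher (camera adjusted p = 0.00175, adjusted p = 0.972 with an estimated correlation). In all 41 genes were higher and 5 lower, and 2281 had an unadjusted p under 0.05. The 46 calls became 37 with the 3 arrays that stood apart left out. The other 2 of the 5 lower genes, Sh3gl2 and LOC100912629, are named after their values were seen and lay under log2 6 in both groups, so no size is given. The count was 11 and 12 without 305.5 mg/kg rats 2 and 3 and 81 without 76.5 mg/kg rat 3, and the calls of Chac1 and Spata2L were lost in 17 and 18 of 29 alternatives. Cdkn3 and Hbb lost theirs in 6 of 29 each, among them with the GAPDH covariate, and Ect2 in 3 of 28.

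Between 153 and 305.5 mg/kg, endothelial and macrophage markers fell as groups. Endothelial markers had a median of -0.49 with 0 of 9 members positive (camera adjusted p = 1.71e-09, adjusted p = 0.0939 with an estimated correlation). Macrophage markers had a median of -0.44 (camera adjusted p = 1.52e-05, adjusted p = 0.318 with an estimated correlation), with 7 members of each passing over the list alone. CAR and PXR targets rose (median 0.20, camera adjusted p = 0.000123, adjusted p = 0.251 with an estimated correlation), as did NRF2 genes (camera adjusted p = 0.0148, adjusted p = 0.633 with an estimated correlation) and ATF4 genes (camera adjusted p = 0.0148, adjusted p = 0.558 with an estimated correlation). No single gene passed limma's test with Benjamini-Hochberg adjustment between these doses, where 1338 genes had an unadjusted p under 0.05 and 0 passed an unmoderated test per gene with unequal variances after the same adjustment. Between 76.5 and 153 mg/kg likewise 0 genes passed by either tool, 1134 had an unadjusted p under 0.05, and no list was called. With the 3 arrays that stood apart left out the counts were 0 and 1. Single genes were called from 153 to 305.5 mg/kg without 153 mg/kg rat 2 (1) or 305.5 mg/kg rat 1 (1), and from 76.5 to 153 mg/kg without 153 mg/kg rat 1 (1), 153 mg/kg rat 3 (1) or 76.5 mg/kg rat 1 (9).

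The rank of the dose, from 0 for vehicle to 4 for 611 mg/kg, was used to ask which genes followed dose. Ces2c rose most steadily, by 0.68 ± 0.05 per rank (limma, Benjamini-Hochberg adjusted p = 5.28e-08). Next came the amyloid precursor gene App (0.24 ± 0.03), Dbp (1.10 ± 0.12), the aldehyde oxidase gene Aox1 (0.20 ± 0.02) and the meiotic recombination gene Mnd1 (0.36 ± 0.04), each with adjusted p = 3.57e-05. Slc6a6 fell by 0.77 ± 0.07 per rank (adjusted p = 1.10e-05) and Bmal1 fell by 0.55 ± 0.06 (adjusted p = 2.59e-05). Tubb2a fell by 0.55 ± 0.06, the mitochondrial protease gene Clpx fell by 0.19 ± 0.02 and Npas2 fell by 0.37 ± 0.04 per rank (each adjusted p = 3.57e-05). Over all genes 563 rose and 395 fell with rank, and 3033 had an unadjusted p under 0.05. The lowest dose at which these 958 genes were called against vehicle was 76.5 mg/kg for 23, 153 mg/kg for 67, 305.5 mg/kg for 153 and 611 mg/kg for 531. The other 184 were called at no dose. Over the 12 treated rats alone, a trend chosen, like the genes named from it, after the data were seen, Ces2c (0.54 per rank, adjusted p = 0.0166), Alas1 (0.33, adjusted p = 0.0213), Cyp3a23-3a1 (0.25, adjusted p = 0.0232) and the coiled-coil gene Ccdc34 (adjusted p = 0.0370) rose, the last of them under log2 6 in every group, so without a size. The mannose receptor gene Mrc1 fell by 0.28 per rank (adjusted p = 0.0232), and the other 9 genes named from the full trend were not called. With the 3 arrays that stood apart left out 639 genes rose and 572 fell with rank over all groups. Rising genes numbered 341, 337, 337, 359 and 374 without vehicle rats 1, 4 and 5 and 611 mg/kg rats 2 and 3, and falling genes 262 without vehicle rat 3.

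Several genes, listed here after their values were seen, were called at all 4 doses. Abcc3, Ces2c, Ugt2b1, Dbp, Nr1d1, Nr1d2, the peroxisomal racemase gene Amacr, the kinase gene Sik2, the transcription factor genes Tbx3 and Tfcp2, the phosphatase subunit gene Ppp2r1b and the phosphatase gene Ptpn3 were higher, 12 in number. Cdkn1a, Cry1, Nat8, Slc6a6, Tsc22d3, the kinase gene Nuak2, the lipid transfer gene Stard5, the nuclear envelope gene Syne1, the corepressor gene Tle1 and Zfp64 were lower, 10 in number. Between 305.5 and 611 mg/kg 79 higher genes were shared where independent lists would share 5.39, and 133 lower genes where they would share 5.06. The log2 differences of these doses correlated across genes, which are not independent replicates, at 0.625 with a covariance of 0.0406. Unchanged groups simulated against the same vehicle rats gave 0.376 and 0.00688. With the 5 vehicle rats split between the doses the medians over 10 splits were 0.489 and 0.0352, with 18 higher and 19 lower genes shared. These splits called fewer genes, 17 to 29 higher and 13 to 60 lower at 305.5 mg/kg and 213 to 480 higher and 135 to 205 lower at 611 mg/kg.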

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

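Within the 5 vehicle rats, the gap of the highest or lowest rat to its nearest neighbour was compared with the whole range. This was done for 131 results (93 genes, 34 list scores and 4 array measures). The kind of test was not chosen after a result was seen, but the 93 genes were picked through their results against these same vehicle rats. In 4 genes 1 vehicle rat lay farther out than Dixon's critical ratio of 0.71. The pancreatic-type elastase gene Cela1 was lowest in vehicle rat 4 (10.68 against 10.9 in the nearest rat, ratio 0.819), and the phospholipid exporter gene Abcb4 was highest in vehicle rat 2 (10.36 against 10.27, ratio 0.849). The serine dehydratase-like gene Sdsl was highest in vehicle rat 3 (8.186 against 7.962, ratio 0.77), and the VEGF receptor gene Kdr was lowest in vehicle rat 2 (9.982 against 10.12, ratio 0.767). Chance puts about 1 in 20 groups past this ratio, a rate that need not hold for genes picked through their vehicle values. No rat stood out in all of these genes. The groups of 3 treated rats were not tested in this manner.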

How the results depend on the processing

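Of the gene results picked by the naming rule, 160 were called in the main analysis. These kept direction and call in 4162 of 4633 alternatives, lost the call in 471 and reversed in 0. They were picked for large changes or small p, so they do not stand for all called genes. Welch's test and the stricter thresholds were not among these alternatives. Of 4052 alternatives over 136 list results, 3904 gave the same call, 96 lost it, 49 gained one and 3 reversed. Only 5, 5, 9 and 12 of the 34 lists were called in the main analysis, from the lowest to the highest dose. The 96 losses come from these called lists alone, and for the others the same call means none again. Small groups limit the counts. In the simulated 611 mg/kg comparison, the only one simulated, 64.8% of changes of 0.5 were recovered. Dim signals, such as those of lymphocyte and neutrophil markers, carried little information. For each list called against vehicle the highest adjusted p over its alternatives was that of camera with an estimated correlation, and the lowest for the cell cycle list at 611 mg/kg was 6.69e-17. Fry kept 0 of the 5 lists that camera called at 76.5 mg/kg, 1 of 5 at 153 mg/kg, 7 of 9 at 305.5 mg/kg and 8 of 12 at 611 mg/kg. It lost PPARA and cell cycle genes at 305.5 mg/kg and PPARA, cholesterol synthesis, macrophage and lymphocyte lists at 611 mg/kg. Fry alone called the clock list at the 3 higher doses, esterases at 305.5 mg/kg (adjusted p = 0.0447) and heme, pancreas and adipocyte lists at 611 mg/kg. Between 153 and 305.5 mg/kg it kept only the endothelial call, and between 305.5 and 611 mg/kg those of cell cycle and red cell genes, with esterases and heme enzymes added (each adjusted p = 0.0349). Leaving out 76.5 mg/kg rats 2 and 3 left 1 rat, assumed to vary like the other groups. The rats of different groups are different animals, and only 10 of 30 pairs with the same number had residual correlations over 0.1, with a mean of 0.0193 against -0.00648 for other pairs, so the numbers were not taken as pairs. However, 10 of 15 rats correlated best with rats of their own number, a hint from the data, so something shared by these rats stays open.

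Counts of higher and lower genes are given from the lowest to the highest dose. Array weights gave 363 and 333, 252 and 146, 438 and 676, and 1206 and 678, with 148, 210 and 333 genes between neighbouring doses and 641 falling with rank. They gave 76.5 mg/kg rat 1 a weight of 5.04 and the 3 arrays that stood apart 0.307, 0.267 and 0.309. A replicate block gave 8 and 7, 23 and 26, 60 and 138, and 215 and 172, with 157 rising and 170 falling. Without the 3 arrays, chosen after the data were seen, counts were 9 and 2, 209 and 105, and 292 and 486 at the 3 lower doses, and 1 gene differed between 76.5 and 153 mg/kg. The GAPDH covariate, also chosen then, gave 33 higher genes at 76.5 mg/kg, 129 at 153 mg/kg and 20 between 305.5 and 611 mg/kg. The mean over probe sets gave 13 higher genes at 76.5 mg/kg, omission of the dimmest 40% gave 13 genes between 305.5 and 611 mg/kg, and all probe sets gave 1 between 76.5 and 153 mg/kg. Fits of only the 2 groups compared gave 4 and 2 at 76.5, 220 and 109 at 153 and 237 and 401 at 305.5 mg/kg, and 12 between 305.5 and 611 mg/kg. The cause of these shifts was not tested.

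By construction, stricter thresholds left fewer genes. An absolute change of at least 1 left 7 and 5, 21 and 13, 27 and 37, and 77 and 41, with 23 between 305.5 and 611 mg/kg and 48 rising and 44 falling. An adjusted p under 0.01 left 3 and 1, 23 and 14, 45 and 75, and 204 and 126, with 12 between 305.5 and 611 mg/kg and 152 rising and 136 falling. Welch's test, without shared variances, left 0 and 0, 24 and 7, 9 and 12, and 60 and 46, and 0 between 305.5 and 611 mg/kg. With the dose in mg/kg 255 genes fell. Without the 611 mg/kg group 111 rose and 179 fell, and without the vehicle group, with fewer rats, 4 rose and 1 fell.

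Leaving out 1 rat at a time gave 8 to 49 higher and 3 to 46 lower genes at 76.5 mg/kg, 18 to 114 and 11 to 73 at 153 mg/kg, 49 to 189 and 86 to 336 at 305.5 mg/kg, and 257 to 1033 and 169 to 455 at 611 mg/kg. Between neighbouring doses it gave 0 to 9, 0 to 1 and 11 to 81 genes, and for the slope 337 to 762 rising and 262 to 481 falling. Cholesterol synthesis at 76.5 mg/kg reversed to higher with array weights (adjusted p = 2.42e-07) and without the 3 arrays (adjusted p = 1.55e-10), where bile acid genes also reversed to higher (adjusted p = 0.0149), and the cause was not tested.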

Other observations

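Single rats within a dose differed in several gene groups. Rat 3 at 76.5 mg/kg had an acute phase and inflammation score of 0.80, against -0.20 and -0.18 in rats 1 and 2 of its dose, and a neutrophil marker score of 1.02, against 0.03 and -0.14. Its array was among the 3 that stood apart. Bile acid genes in the same rat scored -0.43, against 0.26 and 0.15. Cholesterol synthesis genes split the rats within a dose, with 0.51, -0.19 and -0.39 at 76.5 mg/kg, -0.41, -0.13 and 0.40 at 153 mg/kg and -0.40, 0.17 and 0.26 at 305.5 mg/kg, whereas the 3 rats at 611 mg/kg scored 0.37, 0.30 and 0.39.

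The regroupings of rats that follow were chosen before the data were examined, and the tests of the clock, cell cycle and cell type patterns only after those results were seen. Genes called against vehicle were counted for every split of each dose's 8 rats into 3 and 5. A count as high as the real one came from 1 of the 56 splits at 76.5 mg/kg (38 genes, highest other 17) and 1 of the 56 splits at 153 mg/kg (106, highest other 0). It came from 1 of the 56 splits at 305.5 mg/kg (316, highest other 0) and 1 of the 56 splits at 611 mg/kg (1060, highest other 6), in each case the real split itself. The number of called lists was reached in 37 of the 56 splits at 76.5 mg/kg (5 lists, highest other 14) and 29 of the 56 splits at 153 mg/kg (5, highest other 11). It was reached in 10 of the 56 splits at 305.5 mg/kg (9, highest other 11) and 5 of the 56 splits at 611 mg/kg (12, highest other 13), so chance was not excluded for the number of lists at any dose. For single lists, a camera p as small as the real one came from 1 of the 56 splits for CAR and PXR targets at both 305.5 and 611 mg/kg, for the clock list at 153, 305.5 and 611 mg/kg, which fry called and camera did not, and for red cell markers at 611 mg/kg. At 305.5 and 611 mg/kg it came from 2 and 4 splits for growth hormone and STAT5 genes, 5 and 3 for endothelial, 8 and 6 for stellate cell and 9 and 21 for macrophage markers. For NRF2 genes it came from 4 and 7, for PPARA targets from 14 and 14 and for cell cycle genes from 26 and 6. It came from 4 for ATF4 genes at 305.5 mg/kg, and at 611 mg/kg from 2 for esterases, 6 for cholesterol synthesis and 15 for lymphocyte markers. At 76.5 and 153 mg/kg every called list was matched by at least 3 splits. Of 100 orders of all 17 rats, 1, the real one, called as many genes with dose rank (958, highest other 17). Between neighbouring doses the 10 splits were too few to tell: 0 genes with 1 as the highest other from 76.5 to 153 mg/kg (10 splits as high), 0 with 0 from 153 to 305.5 mg/kg (10), and 46 with 4 from 305.5 to 611 mg/kg (1).

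Clock genes stood apart from vehicle at every dose, with Nr1d1, Nr1d2 and Dbp among those higher and Bmal1 and Npas2 among those lower at 611 mg/kg. Of 13 clock genes with a known daytime course, 11 differed in the direction of a later phase at 611 mg/kg, but 9 of the 13 were the called genes that prompted the question. Of the other 4, 2 differed in that direction, so a later clock phase at necropsy stays open. Necropsy times are not given in the sources used here, so a difference in time of day could also reach genes outside the clock list. A score of these genes averaged 0.87 ± 0.20, 1.24 ± 0.32, 1.44 ± 0.08 and 1.495 ± 0.09 (SD, n = 3 each) from the lowest to the highest dose, against 0 ± 0.05 in vehicle (n = 5). Over the 12 treated rats it rose by 0.21 per rank (two-sided exact permutation p = 0.00272, 369600 arrangements), which an effect of the compound that grows with dose would also give. Both explanations stay open, and an order of necropsy that followed dose could give the same slope.

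Cell cycle genes were higher at 611 mg/kg in all 3 rats, with the smallest score in rat 2 (0.45 against 1.12 and 0.61), whose array had the largest 3' minus 5' control differences. Without that rat the list had a median of 0.88 with 15 members called higher (camera adjusted p = 6.69e-17, adjusted p = 0.0708 with an estimated correlation), which argues against low RNA quality as the source. The 31 macrophage, lymphocyte, neutrophil and red cell markers had a median of -0.22, with 1 of them above 0. As a set they gave no sign of more such cells. Many were dim: 21, with all 17 lymphocyte and neutrophil markers, lay under log2 8, a looser bound than the log2 6 used for sizes. Lower markers of whole cell types do not exclude division in a small share of those cells, so dividing immune or blood cells stay open. Which liver cells carried these transcripts could not be read from whole pieces.

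Markers of endothelial cells, stellate cells and macrophages were lower together at 305.5 and 611 mg/kg. The fall was least even for macrophages at 611 mg/kg. There the macrophage mean lay below every vehicle rat in 1 of 3 rats, and 21 of the 56 splits gave as small a camera p. Over the 6 rats of both doses the 3 medians were -0.38 (9 of 9 members below 0), -0.41 (12 of 12) and -0.36 (10 of 10), with SE over members from 0.0263 to 0.0553, which restates the pattern. A smaller share of all other cell types stays open, as does lower expression within these cells, which was not tested apart. Without 611 mg/kg rat 2 the 30 markers above a mean log2 of 6 had a median of -0.39. The SE over these markers, 0.0272, treats markers of the same rats as independent and measures no spread between rats. At 305.5 mg/kg the endothelial and stellate means lay below every vehicle rat in 3 of 3 rats and the macrophage mean in 2 of 3. That group does not hold the array of 611 mg/kg rat 2, which argues against low RNA quality of this array as the source. Of 24 cholangiocyte, lymphocyte and neutrophil markers 13 lay at or under log2 6 and 23 under 8, so those cells could not show whether every type was lower.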
